A study of Homo sapiens with 14 samples.

How the data were processed

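Gene expression was measured in Hep3B cells, a human hepatoma line, with 1-colour Affymetrix whole-transcript arrays. Per the labels' protocols, confluent cells were starved of serum for 16 h and treated for 4 h, each bone morphogenetic protein (BMP) was held with its inhibitor for 3 h at 20 C before it was added, Noggin was given at a 10-fold and RGMc at a 20-fold molar excess, and 100 ng of total RNA was amplified and labelled with biotin. The 14 arrays form 7 groups of 2: untreated, BMP2, BMP2 with Noggin, BMP2 with RGMc, BMP6, BMP6 with Noggin and BMP6 with RGMc. No arm received Noggin or RGMc without a BMP. The labels give the 3 h hold at 20 C for the inhibitor arms only. Each inhibitor arm may therefore differ from its ligand arm by that hold as well, while the Noggin and RGMc arms share it. Nothing in the labels says whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

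The deposited values are log2 expression levels for 33268 probe sets, rounded to 2 decimals. They were made with RMA in Affymetrix Expression Console, per the submitters' processing notes. The versions are not given in the sources used here. RMA subtracts background, gives all arrays the same distribution of probe intensities and sums probes into probe sets, so a change shared by most transcripts would be removed and large differences in dim or very bright probe sets are compressed. The values were used as deposited, without another normalization.

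Probe sets were named through the platform annotation. Of the 33268 probe sets, 19457 had 1 gene symbol, 1751 had several and 12060 had none there. Probe sets with several symbols were not named. The Entrez identifier of 19426 of the 1-symbol probe sets was found in the RefSeq gene table, and 0 symbols needed an update. For 767 genes with several such probe sets, the one with the highest mean over the 14 arrays was kept, which left 18416 genes. The files name no genome build, and no coordinates are given.

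Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). All 14 arrays entered 1 fit with a mean per group and no covariate, which gave 7 residual degrees of freedom and 5.87 prior degrees of freedom and assumed the same spread in every group. The p-values were adjusted by the Benjamini-Hochberg method over the 18416 genes of each comparison, and a gene was called at an adjusted p below 0.05. If no gene changed, a share of about 0.05 of the 18416 genes would on average have an unadjusted p below 0.05. Counts above that share leave room for changes that missed the threshold. There were 15 comparisons. They set each ligand against untreated cells, the ligands against each other, each inhibitor arm against its ligand and against untreated cells, and RGMc against Noggin, and 2 of them tested whether an inhibitor acted differently on the 2 ligands. Errors printed as SE come from this fit. SDs are those of the 2 arrays of a group.

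Gene lists were tested with limma's camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists of a comparison. The lists were BMP/SMAD1-5-9 target genes, BMP receptors and SMAD machinery, BMP ligands with the RGM family and extracellular antagonists, iron metabolism, TGF-beta/SMAD2-3 target genes, Notch pathway target genes, IL-6/STAT3 and acute-phase genes, NF-kappaB inflammatory genes, interferon-stimulated genes, immediate-early genes, hepatocyte genes, cholesterol synthesis and uptake, DNA replication and mitosis, the unfolded protein and amino acid stress response, epithelial-mesenchymal transition, p53 target genes and apoptosis, and markers of fibroblasts and stellate cells, endothelial cells, leukocytes and biliary cells. They held 455 distinct genes, of which 426 were measured, and some genes stand in more than 1 list. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. For each of 6 main comparisons that rule names the 10 largest rises and the 10 largest falls among called genes whose 2 groups of arrays did not overlap. It adds the called members of the BMP target and iron lists there. In the other comparisons it names the 5 largest each way among called genes, without the condition on overlap. HAMP, ID1, SMAD6 and SMAD7 are named throughout, and as examples of a list its members with the smallest adjusted p. Genes named outside the rule are said to be so.

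How far an inhibitor turned back a ligand's response was read on genes selected with the other ligand, since genes selected on the same ligand arrays would move back by selection alone. The median change with inhibitor was taken over those genes, and its spread is the SD between arrays. Such genes were counted as opposite when they moved against the ligand's direction at an adjusted p below 0.05 over the selected genes alone. The comparisons of BMP2 and of BMP6 with untreated cells share both untreated arrays, so the overlap of their calls was set beside 100 simulations of unchanged groups against those arrays and beside the overlap of independent lists. Taking as many genes from each simulation as were called and splitting the untreated arrays between the ligands were added after the overlap had been seen.

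The fit, the list test and the reading of reversal were tested on simulated data. For BMP2 against untreated with 18416 genes, a simulated log2 change of 0.5 was called with its sign for 54 of 67 genes (80.6%), one of 1 for 67 of 67 and one of 2 for 66 of 66, with 8 false calls (4.10% of calls). A list shifted by 0.3 was called and 0 others were. The simulated genes varied independently of each other, so this does not measure false list calls where genes of a list vary together. A simulated full reversal of -1 was recovered as -0.997.

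The alternatives were to test all probe sets, to leave out the genes below the median level, to apply cyclic loess to the values, to use eBayes with a trend and robust prior, to weight each array by its fit (limma's arrayWeights), to fit only the arrays compared, to add the replicate number as a block, to ask for a fold change of at least 1.5 as well, to estimate the correlation within lists, and to leave out each array in turn. Where that left a group with 1 array, the array was assumed to vary like those of the other groups. The array weights came out equal for both arrays of each group (0.61 for each BMP6 array). They therefore weighted groups and could not set 1 array below its partner. All value columns of the deposited table were matched to samples and used.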

Results

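Expression of 18416 genes was compared across 14 arrays from Hep3B cells, a human hepatoma line, in 7 groups of 2. The design asks how RGMc (hemojuvelin, a BMP-binding protein of the liver and muscle) changes the transcriptional response to BMP2 and BMP6, with Noggin, an extracellular BMP antagonist, as the reference inhibitor. Array medians lay between 7.25 and 7.33 on the log2 scale. The Pearson correlation between the 2 arrays of a group, across genes, ran from 0.99586 (BMP6) to 0.997981 (BMP6 with Noggin), and between arrays of different groups from 0.99132 to 0.997866. No pair of arrays held identical values. The first principal component held 33.9% of the variance and the second 19.8%. BMP6 replicate 1 stood apart from its partner. It scored 6.27 on the first component against -8.75 for BMP6 replicate 2, and the SD of the difference between these arrays was 0.189, against 0.124 to 0.156 in the other groups. All 4 RGMc arrays (6.03 to 16.90) and both arrays of BMP2 with Noggin (4.34 and 10.51) also lay on the positive side of that component, while the untreated, BMP2 and BMP6 with Noggin arrays lay between -16.24 and -5.31.

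The first question was what BMP2 does to these cells within 4 h. BMP2 raised the genes that serve as textbook readouts of BMP signalling. ID1, which encodes an inhibitor of basic helix-loop-helix transcription factors, rose by 3.72 log2 units (SE 0.15, 13.2-fold, limma adjusted p = 9.9e-09), from 8.19 ± 0.34 to 11.91 ± 0.13 (SD, n = 2), and its relatives ID3, ID4 and ID2 rose by 3.47, 1.76 and 0.98. The inhibitory SMADs that feed back on the pathway rose as well, SMAD6 by 2.73 (SE 0.14) and SMAD7 by 2.11 (SE 0.11), as did the decoy receptor BAMBI (2.03), the receptor SMAD SMAD9 (1.87) and the transcription factors ATOH8 (1.77), HEY1 (1.99), GATA2 (1.66), SNAI1 (1.47) and SNAI2 (1.31). Among the largest rises outside the target list were the neutral amino acid transporter SLC6A19 (2.84), the growth hormone receptor GHR (2.04), the long non-coding RNA UCA1 (2.02) and RASSF5 (1.96). HAMP, which encodes the iron hormone hepcidin and is a BMP target in hepatocytes, was at 7.30 ± 0.07 against 6.94 ± 0.05 in untreated cells (SD, n = 2), a difference of 0.37 (SE 0.10) that missed the threshold (limma adjusted p = 0.069).

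Fewer genes fell with BMP2, and by less. The largest falls were those of RASSF9 (-1.26, SE 0.14), the kinase PLK2 (-1.10), the retinoic acid receptor RARB (-1.03), LYPD1 (-0.97), the epidermal growth factor family ligand EREG (-0.94), CDH10 (-0.90), the TGF-beta family member GDF15 (-0.82), ELF5 (-0.79), DCLK2 (-0.78) and the chemokine CXCL12 (-0.76). In all, 521 genes were called, 375 higher and 146 lower, with 45 raised and 3 lowered at least 2-fold. The count fell when any of the 4 arrays was left out, to 271 and 262 without untreated replicates 1 and 2 and to 324 and 332 without BMP2 replicates 1 and 2. PLK2 lost its call without BMP2 replicate 2 (-0.95).

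Of the 33 measured BMP target genes, 17 rose and 0 fell with BMP2 (20 and 1 adjusted over the list alone, camera FDR = 6.0e-34, adjusted p = 0.00021 with an estimated correlation). JUNB (1.29) and SKIL (0.95) were among them. HES1 (0.39) and KLF10 (0.41) passed the threshold too, but HES1 lost its call without either untreated array (0.40 and 0.39) or BMP2 replicate 1 (0.30), and KLF10 without any single array of the comparison (0.38 to 0.44). Of 24 genes of the receptor and SMAD machinery, SMAD1 (0.56, SE 0.08), BMPR2 (0.71), SKI (0.35), ACVR1 (0.34) and NEO1 rose and the type II TGF-beta receptor TGFBR2 fell by 0.74 (7 higher and 2 lower adjusted over the list alone). That list's camera FDR was 0.031, with adjusted p = 0.55 with an estimated correlation. Of 32 iron genes, FURIN (0.66), the hemojuvelin receptor NEO1 (0.34) and haem oxygenase HMOX1 (0.36) rose (6 higher and 2 lower adjusted over the list alone, camera FDR = 0.22). NEO1 lost its call without either untreated array (0.33 and 0.35) or BMP2 replicate 1 (0.24), and HMOX1 without any single array (0.29 to 0.43). With only the arrays compared in the fit, HES1, NEO1 and HMOX1 missed the threshold at the same log2 changes. The Notch targets rose as a group with 3 of 15 called, HEY1, HES1 and CCND1 (0.44), and 4 higher adjusted over the list alone (camera FDR = 3.0e-04, adjusted p = 0.24 with an estimated correlation). The epithelial-mesenchymal list had 5 of 21 called, led by SNAI1, SNAI2, LEF1 (0.96) and vimentin VIM (0.52), with 5 adjusted over the list alone (camera FDR = 0.0025, adjusted p = 0.23 with an estimated correlation). HEY1, HES1, SNAI1 and SNAI2 are also in the BMP target list. In this and later comparisons the Notch and epithelial-mesenchymal lists therefore partly repeat the BMP target result. With BMP2 the Notch list had a median of 0.11 and a mean of 0.24. The epithelial-mesenchymal list had a median of 0.005 and a mean of 0.21.

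Smaller shifts were seen in a pair of lists. DNA replication genes had 1 of 34 called, MCM3 (0.45), and 1 adjusted over the list alone (camera FDR = 0.012, adjusted p = 0.49 with an estimated correlation). Without BMP2 replicate 1 the camera FDR was 0.18. The unfolded protein and amino acid stress list was lower with 1 rise (CEBPB, 0.41) and 1 fall (TRIB3, -0.31) called among 24 genes and 2 higher and 5 lower adjusted over the list alone (camera FDR = 0.011, adjusted p = 0.28 with an estimated correlation). The receptor and stress lists also left the threshold without untreated replicate 2 (camera FDR = 0.13 and 0.065), the receptor list without BMP2 replicate 1 (0.45) and the stress list without BMP2 replicate 2 (0.054). Cyclic loess ended the calls of the DNA replication and receptor lists (0.084 and 0.062), and leaving out the dimmer genes those of the DNA replication, receptor, Notch and epithelial-mesenchymal lists (0.12, 0.062, 0.062 and 0.14). The remaining lists did not pass, but TGF-beta targets did without BMP2 replicate 2 (0.047) and BMP ligands and antagonists without the dimmer genes (0.0023). Camera FDRs were 0.12 for TGF-beta targets, whose median (-0.01) and mean (0.11) differ in sign, 0.44 for BMP ligands and antagonists, 0.89 for IL-6 and acute-phase genes, 0.94 for NF-kappaB genes, 0.44 for interferon-stimulated genes, 0.54 for immediate-early genes, 0.94 for hepatocyte genes, 0.94 for cholesterol genes and 0.61 for p53 targets. For markers of other cell types they were 0.52 (fibroblasts and stellate cells), 0.54 (endothelial cells), 0.54 (leukocytes) and 0.44 (biliary cells). The immediate-early list held called genes of both directions, with DUSP1 (1.52) and JUNB up and DUSP6 (-0.76) down. The p53 list held rises of the pro-apoptotic BCL2L11 (0.93) and GADD45B (0.84). Its median (-0.04) and mean (0.07) differ in sign, as do those of the NF-kappaB list (0.02 and -0.001) and the immediate-early list (-0.03 and 0.06).

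**Figure D1:**
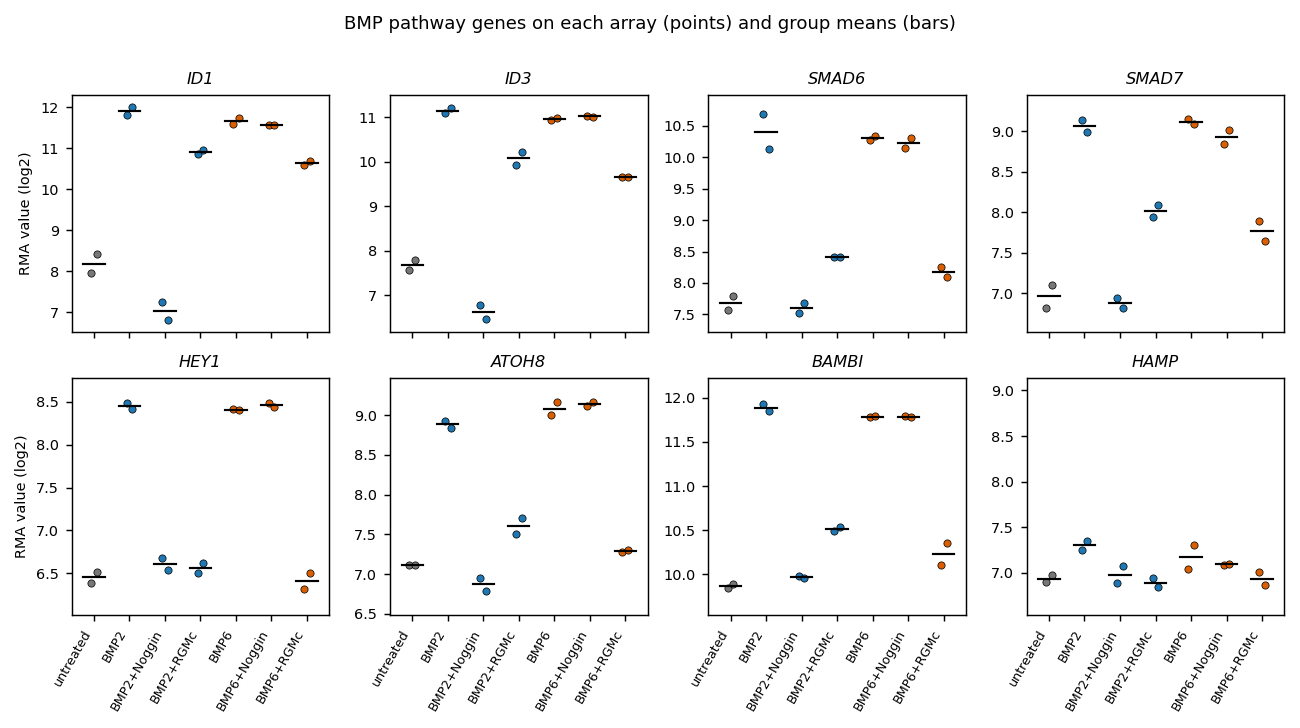
RMA values (log2) of 8 BMP pathway genes on each array (points, 2 per group) with group means (bars) for the 7 groups, coloured by ligand. ID1 reached 11.91 with BMP2 and 11.68 with BMP6, 7.04 with BMP2 and Noggin, 11.58 with BMP6 and Noggin, and 10.92 and 10.64 with RGMc, while HAMP stayed between 6.89 and 7.30 in every group mean.

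BMP6 raised the same leading genes. ID1 rose by 3.49 log2 units (SE 0.15, 11.2-fold, limma adjusted p = 1.6e-08), ID3 by 3.28 (SE 0.12), SLC6A19 by 2.65, SMAD6 by 2.63, SMAD7 by 2.16, GHR by 2.00, ATOH8 by 1.97, HEY1 by 1.95, BAMBI by 1.92 and the dermatan sulfate epimerase gene DSE by 1.89. SMAD9 (1.81), GATA2 (1.65), ID4 (1.48), SNAI1 (1.45), SNAI2 (1.35), SKIL (0.83), JUNB (0.82) and ID2 (0.81) followed. The falls were led by the immediate-early transcription factor EGR1 (-0.92, SE 0.14), RASSF9 (-0.88), LYPD1 (-0.80), GDF15 (-0.79), CDH10 (-0.75), EREG (-0.71), PLK2 (-0.71), TENT5C (-0.70), TGFBR2 (-0.65) and BTG1 (-0.62). HAMP differed from untreated by 0.24 (SE 0.10, limma adjusted p = 0.20).

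Against untreated cells, 691 genes were called with BMP6, 562 higher and 129 lower, with 43 raised and 0 lowered at least 2-fold. The count moved with each array. It was 286 and 256 without untreated replicates 1 and 2, 310 without BMP6 replicate 1, the array that stood apart, and 1874 without BMP6 replicate 2. Of the calls made with all arrays, 284 were kept without BMP6 replicate 1 and 0 turned direction. PLK2 lost its call without untreated replicate 1 (-0.68), untreated replicate 2 (-0.73) or BMP6 replicate 2 (-0.46), and under cyclic loess (-0.69), and TENT5C without untreated replicate 2 (-0.64). With only the arrays compared in the fit, EGR1, RASSF9, CDH10, PLK2, TENT5C, BTG1, HES1 (0.37) and NEO1 (0.45) missed the threshold at the same log2 changes, as did PLK2 with array weights.

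Of the 33 BMP targets, 16 rose and 0 fell with BMP6 (19 and 2 adjusted over the list alone, camera FDR = 3.3e-17, adjusted p = 0.0020 with an estimated correlation). HES1 (0.37), which was one of them, lost its call without either untreated array (0.38 and 0.37) or BMP6 replicate 1 (0.35). Among iron genes FURIN (0.61) and NEO1 (0.45) rose, with 4 higher adjusted over the list alone (camera FDR = 0.086). NEO1 lost its call without untreated replicate 1 (0.44) or BMP6 replicate 1 (0.41). In the receptor and SMAD list 7 genes rose, among them SMAD1 (0.78) and BMPR2 (0.77), and TGFBR2 fell (9 and 1 adjusted over the list alone, camera FDR = 0.0052, adjusted p = 0.34 with an estimated correlation). The Notch list had 4 of 15 genes up, HEY1, NRARP (0.39), HES1 and CCND1 (0.42), and 6 adjusted over the list alone (camera FDR = 0.022, adjusted p = 0.35 with an estimated correlation). Without BMP6 replicate 2 its camera FDR was 0.31. DNA replication genes had 1 called, MCM3 (0.45), and 6 adjusted over the list alone (camera FDR = 6.6e-04, adjusted p = 0.27 with an estimated correlation). BMP ligands and antagonists had 1 rise, follistatin FST (0.39), and 3 falls, GDF15, RGMB (-0.31) and GDF2 (-0.28), and the same counts adjusted over the list alone (camera FDR = 0.0070, adjusted p = 0.27 with an estimated correlation). Without untreated replicate 1 its camera FDR was 0.065. Cyclic loess ended the calls of the DNA replication and ligand lists (camera FDR = 0.075 and 0.057), and leaving out the dimmer genes those of the DNA replication and Notch lists (0.058 and 0.087). The number of lists past the threshold was 5, and 10 without BMP6 replicate 1.

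Whether the ligands differ was then tested directly. No gene was called between BMP6 and BMP2 with limma, where 1843 genes had an unadjusted p below 0.05 and the smallest adjusted p was 0.27. ID1 differed by -0.24 (SE 0.15), SMAD6 by -0.11 (SE 0.14), SMAD7 by 0.06 (SE 0.11) and HAMP by -0.13 (SE 0.10). Without BMP6 replicate 2, 35 genes were called. Camera placed 6 lists past the threshold at the preset correlation and 0 with an estimated one. BMP targets (mean -0.10, FDR = 4.4e-04), immediate-early genes (-0.09, 0.0016), NF-kappaB genes (-0.08, 0.012), BMP ligands and antagonists (-0.06, 0.015) and TGF-beta targets (-0.07, 0.025) were lower with BMP6, and the stress list was higher (0.13, 1.3e-04). Their adjusted p with an estimated correlation ran from 0.086 for the BMP target, NF-kappaB and stress lists to 0.31 for the TGF-beta list. Without BMP6 replicate 2 the ligand, TGF-beta, NF-kappaB and immediate-early lists left the threshold (camera FDR = 0.067, 0.066, 0.11 and 0.066). Without BMP2 replicate 1 the ligand, TGF-beta and NF-kappaB lists did (0.095, 0.34 and 0.095), and without BMP6 replicate 1 the TGF-beta list (0.086). The ligand list also did under cyclic loess (0.068) and without the dimmer genes (0.22). Some lists entered the threshold instead. Among them were the receptor and SMAD list, higher with BMP6, with a trend and robust prior (camera FDR = 0.036) or without BMP2 replicate 1, and the IL-6 list, lower, without BMP6 replicate 1. Over the 833 genes called with either ligand, 819 had the same sign in both, the median absolute difference was 0.12 and the largest was 0.66. The median half-width of the 95% interval of the difference over these genes was 0.18. Both changes were taken against the same untreated arrays, on which the genes were also selected. That alone raises the agreement of sign, and its size in unchanged groups was not simulated.

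The calls of the 2 ligands overlapped in 326 genes that rose and 53 that fell, with 0 in opposite directions. Independent lists of these sizes would share 11.4 and 1.02. Unchanged groups simulated against the same untreated arrays shared 0, but they gave a mean of 0.02 and 0.04 calls, so that 0 does not measure what the shared controls add. When as many genes as were called were taken from each simulation by the smallest p, a mean of 108 (maximum 133) of the higher and 25.1 (maximum 32) of the lower ones were shared. The correlation of the log2 changes over all genes, which are not independent replicates, was 0.759, against 0.50 in the simulations. The covariance was 0.0248 against 0.00552, an excess of 0.0193. Part of the excess over independent lists may come from the shared controls. With untreated replicate 1 as the control of BMP2 and replicate 2 as that of BMP6, so that no array was shared, the correlation was 0.54 and the calls overlapped in 153 rises and 17 falls, against 2.89 and 0.096 for independent lists. With these controls exchanged the correlation was 0.59 and the overlap 156 and 14, against 2.61 and 0.083, and 0 genes went in opposite directions in either split. The overlap of rises was 177 and 178 without untreated replicates 1 and 2 and 183 without BMP2 replicate 1, and that of falls 24 and 13 without untreated replicates 1 and 2 and 26 without BMP6 replicate 1.

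The next question was how far Noggin blocks each ligand. With BMP2, Noggin lowered the target genes, ID1 and ID3 to below their untreated levels. ID1 fell by 4.88 log2 units (SE 0.15, limma adjusted p = 8.6e-10), from 11.91 ± 0.13 to 7.04 ± 0.30 (SD, n = 2), with ID3 (-4.52, SE 0.12), SMAD6 (-2.81) and SMAD7 (-2.19). SLC6A19 (-2.68), RASSF5 (-2.10), UCA1 (-2.06), the nucleoside transporter SLC29A3 (-2.03), ATOH8 (-2.02), ID4 (-1.99), SMAD9 (-1.97), BAMBI (-1.92), GATA2 (-1.87) and HEY1 (-1.84) fell with them, as did SNAI1 (-1.65), SNAI2 (-1.39), JUNB (-1.23), SKIL (-0.85), ID2 (-0.80) and FURIN (-0.76). Genes that BMP2 had lowered rose, led by PLK2 (1.92, SE 0.17) and RASSF9 (1.59), then EGR1 (1.49), GDF15 (1.22), CDH10 (1.19), LYPD1 (1.15), EREG (1.10), the chemokine receptor CXCR4 (1.06), endothelin EDN1 (1.03) and RARB (1.00). HAMP differed by -0.32 (SE 0.10, limma adjusted p = 0.087).

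In total 850 genes were called between BMP2 with Noggin and BMP2, 451 higher and 399 lower, with 9 raised and 45 lowered at least 2-fold. Under cyclic loess the split was 418 higher and 469 lower, so the direction of the majority rests on the scaling. The count was 410 without BMP2 replicate 2 and 374 without replicate 2 of BMP2 with Noggin. Of the BMP targets 16 fell and 1, BMP4 (0.64), rose (21 and 1 adjusted over the list alone, camera FDR = 1.2e-28, adjusted p = 3.8e-04 with an estimated correlation). HES1 (-0.32) lost its call without BMP2 replicate 1 (-0.22) or replicate 1 or 2 of BMP2 with Noggin (-0.38 and -0.26) and with only the arrays compared in the fit, and the iron gene HMOX1 (-0.43) without the same arrays (-0.36, -0.43 and -0.42). The iron list had 2 falls, FURIN and HMOX1, and 2 adjusted over the list alone (camera FDR = 0.29). The Notch list had 3 falls, HEY1, CCND1 (-0.45) and HES1, and 5 adjusted over the list alone (camera FDR = 9.1e-04, adjusted p = 0.30 with an estimated correlation). The epithelial-mesenchymal list had 5 falls, led by SNAI1, SNAI2 and LEF1 (-0.85), and 5 adjusted over the list alone (camera FDR = 0.013, adjusted p = 0.30 with an estimated correlation). Cholesterol genes were higher with 0 called by limma (2 adjusted over the list alone, camera FDR = 0.013, adjusted p = 0.41 with an estimated correlation). Without BMP2 replicate 1 the epithelial-mesenchymal and cholesterol lists left the threshold (camera FDR = 0.17 and 0.070), as did the cholesterol list without replicate 2 of BMP2 with Noggin (0.079) and under cyclic loess (0.14). Leaving out the dimmer genes ended both calls (0.36 and 0.16).

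With BMP6 and Noggin the BMP target genes stayed high. ID1 stood at 11.58 ± 0.00 with Noggin and 11.68 ± 0.11 without it (SD, n = 2), a difference of -0.10 (95% interval -0.42 to 0.23). SMAD6 differed by -0.09 (SE 0.14), SMAD7 by -0.19 (SE 0.11) and HAMP by -0.08 (SE 0.10). No gene was called with limma, where 3314 genes had an unadjusted p below 0.05 and the smallest adjusted p was 0.074. That count rested on the BMP6 arrays, being 1 without replicate 1 and 1115 without replicate 2. Only the stress list passed camera, lower as a group (mean -0.14, 0 of 24 genes called by limma and 0 adjusted over the list alone, FDR = 0.0017, adjusted p = 0.45 with an estimated correlation). It left the threshold without BMP6 replicate 2 or replicate 1 of BMP6 with Noggin (camera FDR = 0.058 and 0.063) and without the dimmer genes (0.092).

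The difference between the Noggin effects was itself tested. It was called for 1061 genes, 409 with a more positive and 652 with a more negative change in the BMP6 arm. Under cyclic loess the split was 461 and 458. ID1 led with a difference of 4.78 (SE 0.21, limma adjusted p = 9.3e-08), followed by ID3 (4.59), SMAD6 (2.73), SLC6A19 (2.47), ID4 (2.31) and SMAD7 (2.00), and the opposite sign was led by PLK2 (-2.11), RASSF9 (-1.70), CDH10 (-1.48), EGR1 (-1.40) and EREG (-1.31). HAMP differed by 0.24 (SE 0.14, limma adjusted p = 0.27). The count was 1651 and 282 without BMP2 replicates 1 and 2, 636 and 265 without replicates 1 and 2 of BMP2 with Noggin, 307 and 2902 without BMP6 replicates 1 and 2, and 362 and 276 without replicates 1 and 2 of BMP6 with Noggin. Of the 1061 calls, 298 were kept without BMP6 replicate 1 and 0 turned direction.

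Reversal was also read on genes chosen with the other ligand. Over the 562 genes that BMP6 raised, the median change with Noggin in the BMP2 arm was -0.30 (SD between arrays 0.06), and 356 of them (63.3%) fell at a threshold over these genes. That median was -0.51 and -0.57 without untreated replicates 1 and 2, -0.51 without BMP6 replicate 1 and -0.08 without BMP6 replicate 2, since the choice of genes rests on those arrays. Over the 375 genes that BMP2 raised, the median change with Noggin in the BMP6 arm was -0.09 (SD between arrays 0.02). That median plus or minus the t quantile for 7 degrees of freedom times the SD gave a range of -0.12 to -0.05. The range is rough, since the SD rests on 2 arrays per group and the 7 degrees of freedom belong to the fit of single genes. Of the 375 genes 302 changed below 0, and 0 fell at the threshold of limma over the 375. The median over all genes in that comparison was -0.035, and that of the 375 genes was -0.0166 under cyclic loess. Over the genes lowered by the other ligand, Noggin's median was 0.02 in the BMP2 arm (129 genes) and -0.08 in the BMP6 arm (146 genes). The first of these was 0.57 and 0.64 without untreated replicates 1 and 2, 0.72 without BMP6 replicate 1, -0.09 without BMP6 replicate 2, 0.09 without BMP2 replicate 2, and 0.10 and 0.15 without replicates 1 and 2 of BMP2 with Noggin.

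**Figure D2:**
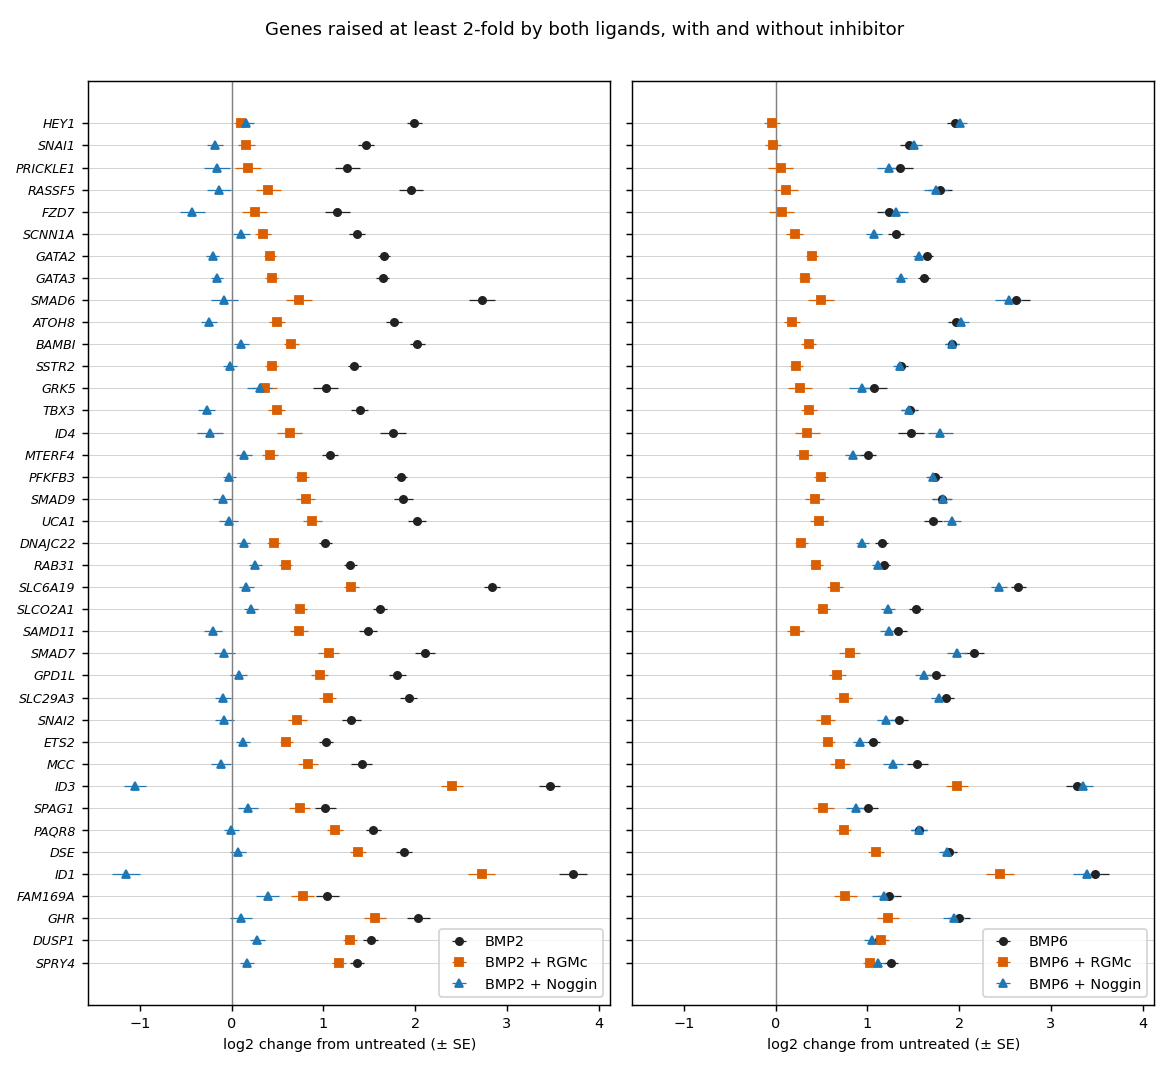
Change from untreated (log2, horizontal axis, bars ± SE) of the 39 genes that both BMP2 (left panel) and BMP6 (right panel) raised at least 2-fold, for the ligand alone (circles), with RGMc (squares) and with Noggin (triangles). Genes are ordered by the share of the log2 rise that RGMc took away in the BMP2 arm. That share ran from 94.7% for HEY1 to 14.6% for SPRY4. The Noggin triangles lie near the ligand circles with BMP6 only.

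RGMc was tested in the same way. It lowered BMP target genes with both ligands, though to different extents. With BMP2, SMAD6 fell by 2.00 log2 units (SE 0.14, limma adjusted p = 6.0e-06), from 10.41 ± 0.40 to 8.42 ± 0.01 (SD, n = 2), HEY1 by 1.89 (SE 0.08), RASSF5 by 1.56, SLC6A19 by 1.54, the Notch ligand DLL4 by 1.41, BAMBI by 1.38, SNAI1 by 1.31, ATOH8 by 1.28, GATA2 by 1.24 and GATA3 by 1.21. ID1 fell by 1.00 (SE 0.15), and ID4 (-1.13), ID3 (-1.07), SMAD9 (-1.07), SMAD7 (-1.05), SNAI2 (-0.59) and FURIN (-0.46) fell too. HAMP fell by 0.41 (SE 0.10, limma adjusted p = 0.034). It lost its call without any single array of the comparison (-0.46 to -0.36) and with array weights, as did ID1 without BMP2 replicate 2 (-0.91), SNAI2 without replicate 1 of BMP2 with RGMc (-0.56) and FURIN without its replicate 2 (-0.38). The genes that rose were led by EGR1 (2.01, SE 0.14, 4.03-fold), PLK2 (1.44), EREG (1.43), the chemokine CXCL8 (1.33), the cystine transporter SLC7A11 (1.32), the olfactory receptor gene OR14J1 (1.28, from 1 of a pair of probe sets with the same values), GPCPD1 (1.26), the chemokine CCL20 (1.17), the vault RNA VTRNA1-1 (1.16) and the glutathione-degrading enzyme CHAC1 (1.13). Part of these rises undid falls with BMP2, of PLK2 (-1.10), EREG (-0.94) and EGR1 (-0.60, limma adjusted p = 0.043). PLK2 stood at 7.84 in untreated cells, 6.74 with BMP2, 8.18 with BMP2 and RGMc and, higher, at 8.66 with BMP2 and Noggin. VTRNA1-1 is a dim probe set, at 4.28 with BMP2 and 5.44 with BMP2 and RGMc, below the lower quartile of these arrays. In the BMP6 arm it did not rise (4.675 with BMP6 and 4.595 with BMP6 and RGMc).

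Between BMP2 with RGMc and BMP2, 603 genes were called, 382 higher and 221 lower, with 13 raised and 18 lowered at least 2-fold. The count was 225 without BMP2 replicate 2, and 360 and 227 without replicates 1 and 2 of BMP2 with RGMc. Of the BMP targets 13 fell and 0 rose (17 and 0 adjusted over the list alone, camera FDR = 3.8e-18, adjusted p = 0.0017 with an estimated correlation). Iron genes had 2 falls, FURIN and HAMP, and 2 adjusted over the list alone (camera FDR = 0.84). NF-kappaB genes had 10 rises, among them ICAM1 (0.96), CXCL8, CXCL1 (0.76) and CCL20, and 1 fall (12 and 1 adjusted over the list alone, camera FDR = 3.0e-10, adjusted p = 0.0017 with an estimated correlation). Immediate-early genes had 8 rises, among them EGR1, IER3 (0.57) and ATF3 (0.66), and 0 falls (15 and 2 adjusted over the list alone, camera FDR = 8.3e-08, adjusted p = 0.022 with an estimated correlation). The unfolded protein and amino acid stress list had 11 rises and 0 falls, led by CHAC1, TRIB3 (0.91), SLC7A11 and SESN2 (0.76), which are targets of the stress factor ATF4 (12 and 0 adjusted over the list alone, camera FDR = 1.5e-12, adjusted p = 0.0061 with an estimated correlation). Cholesterol genes were higher with 1 called, INSIG1 (0.34), and 2 adjusted over the list alone (camera FDR = 0.0012, adjusted p = 0.25 with an estimated correlation). DNA replication genes were lower with 0 called by limma and 0 adjusted over the list alone (camera FDR = 0.0070, adjusted p = 0.37 with an estimated correlation, camera FDR = 0.14 without BMP2 replicate 1). The arrays with RGMc scored 6.03 and 12.85 on the first principal component in this arm, against -5.32 and -13.61 with BMP2 alone.

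With BMP6, RGMc lowered SMAD6 by 2.13 (SE 0.14, limma adjusted p = 2.7e-06), from 10.31 ± 0.05 to 8.18 ± 0.12 (SD, n = 2), and SLC6A19 (-2.00), HEY1 (-1.99), ATOH8 (-1.79), RASSF5 (-1.68), BAMBI (-1.56), DLL4 (-1.54), SNAI1 (-1.48), SMAD9 (-1.39) and SMAD7 (-1.36) fell with it. ID3 fell by 1.31, GATA2 by 1.25, ID4 by 1.13, ID1 by 1.04 (SE 0.15), SNAI2 by 0.80 and FURIN by 0.52. HAMP differed by -0.24 (SE 0.10, limma adjusted p = 0.24). EGR1 rose by 2.46 (SE 0.14, 5.48-fold), CXCL8 by 1.77, CCL20 by 1.46, GPCPD1 by 1.41, PLK2 by 1.34, EREG by 1.33, GDF15 by 1.31, OR14J1 by 1.26, CHAC1 by 1.10 and CXCL1 by 1.06. EGR1, GDF15, EREG and PLK2 were among the 10 largest falls with BMP6 alone.

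In this arm 716 genes were called, 312 higher and 404 lower, with 10 raised and 30 lowered at least 2-fold. The count was 245 and 415 without replicates 1 and 2 of BMP6 with RGMc. Without BMP6 replicate 1 it was 599, of which 433 were among the 716 and 0 turned direction. Of the BMP targets 13 fell and 1, RUNX2 (0.51), rose (16 and 2 adjusted over the list alone, camera FDR = 1.0e-14, adjusted p = 0.0019 with an estimated correlation). RUNX2 lost its call without BMP6 replicate 1 (0.35) or replicate 1 of BMP6 with RGMc (0.30), and RUNX2 and SKIL lost theirs with array weights. With only the arrays compared in the fit, RUNX2, SKIL, NEO1 and FURIN missed the threshold at the same log2 changes. SKIL (-0.42) lost it without BMP6 replicate 1 (-0.31) or either array with RGMc (-0.51 and -0.32), and the iron gene NEO1 (-0.38) without the same arrays (-0.34, -0.36 and -0.40). The iron list had 2 falls, FURIN and NEO1, and 3 adjusted over the list alone (camera FDR = 0.17). NF-kappaB genes had 12 rises and 0 falls (16 and 1 adjusted over the list alone, camera FDR = 2.9e-18, adjusted p = 4.5e-04 with an estimated correlation), with ICAM1 at 0.90 and TNFAIP3 at 0.88. Immediate-early genes had 13 rises and 0 falls (15 and 0 adjusted over the list alone, camera FDR = 1.3e-16, adjusted p = 0.0029 with an estimated correlation), with IER3 at 0.94 and KLF6 at 0.70. The stress list had 8 rises and 0 falls (10 and 1 adjusted over the list alone, camera FDR = 4.6e-11, adjusted p = 0.0073 with an estimated correlation), with DDIT4 at 0.81 and DDIT3 at 0.81. The arrays with RGMc scored 16.90 and 11.70 on the first principal component, against 6.27 and -8.75 with BMP6 alone. Cholesterol genes had 2 rises, INSIG1 (0.45) and MVK (0.30), and 5 adjusted over the list alone (camera FDR = 7.8e-08, adjusted p = 0.043 with an estimated correlation).

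The other lists that camera called in the BMP6 arm were lost with an estimated correlation. The receptor and SMAD list had 6 falls, led by SMAD1 (-0.47) and SKI (-0.39), with 1 higher and 8 lower adjusted over the list alone (FDR = 6.9e-04, adjusted p = 0.15 with an estimated correlation). TGF-beta targets had 6 rises, led by CCN1 (0.93) and THBS1 (0.63), and 1 fall, with 7 and 1 adjusted over the list alone (FDR = 0.0023, adjusted p = 0.14 with an estimated correlation). DNA replication genes had 2 falls, MCM3 (-0.32) and KIF20A (-0.32), with 1 higher and 13 lower adjusted over the list alone (FDR = 6.6e-05, adjusted p = 0.11 with an estimated correlation). The p53 list had 3 falls, led by BCL2L11 (-1.01), and 4 adjusted over the list alone (FDR = 0.040, adjusted p = 0.11 with an estimated correlation), and left the threshold without BMP6 replicate 1 or replicate 2 of BMP6 with RGMc (FDR = 0.071 and 0.060).

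The RGMc effects of the 2 arms, which share no array, overlapped in 175 rises and 180 falls with 0 genes in opposite directions. Independent lists would share 6.47 and 4.85. Across genes, which are not independent replicates, the log2 changes correlated at 0.629 over all genes and 0.918 over those called in either arm. No gene was called with limma for a difference between the arms, where 888 had an unadjusted p below 0.05 and the smallest adjusted p was 0.33, and 1 was called without BMP6 replicate 2. ID1 differed by -0.05 (SE 0.21), SMAD6 by -0.14 (SE 0.20), SMAD7 by -0.31 (SE 0.16) and HAMP by 0.18 (SE 0.14). Over the 375 genes that BMP2 raised, the median change with RGMc in the BMP6 arm was -0.33 (SD between arrays 0.02), and 265 (70.7%) fell at a threshold over these genes. Over the 562 that BMP6 raised, the median in the BMP2 arm was -0.17 (SD between arrays 0.06), and 249 (44.3%) fell. The second median was -0.30 and -0.34 without untreated replicates 1 and 2, -0.31 and -0.02 without BMP6 replicates 1 and 2, and -0.11 without BMP2 replicate 1. Of the genes lowered by the other ligand, the median with RGMc was 0.18 in the BMP6 arm and 0.01 in the BMP2 arm, the latter being 0.11 and 0.18 without untreated replicates 1 and 2, 0.21 without BMP6 replicate 1 and -0.09 without BMP6 replicate 2.

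**Figure D3:**
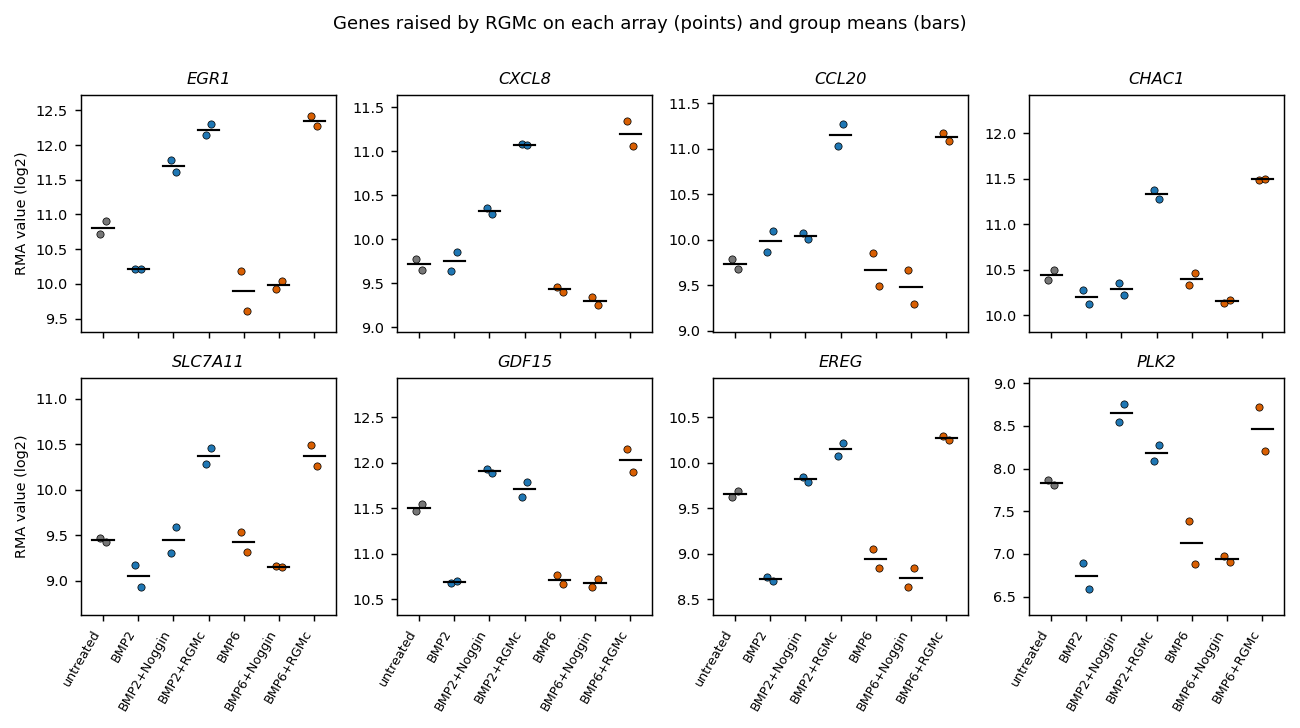
RMA values (log2) of 8 genes that RGMc raised above the ligand alone, on each array (points, 2 per group) with group means (bars). The 7 groups are coloured by ligand. GDF15 and PLK2 stood higher with BMP2 and Noggin (11.91 and 8.655) than with BMP2 and RGMc (11.705 and 8.18). The other genes shown stood higher with BMP2 and RGMc. EGR1 stood at 10.81 in untreated cells, 11.70 with BMP2 and Noggin, and 12.22 and 12.35 with RGMc and BMP2 or BMP6, and CXCL8 at 9.72 in untreated cells, 10.33 with BMP2 and Noggin, and 11.08 and 11.20 with RGMc.

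Against untreated cells, BMP2 with Noggin left 2 genes called by limma, both lower, ID3 (-1.06, SE 0.12, adjusted p = 0.011) and ID1 (-1.16, SE 0.15, adjusted p = 0.033). SMAD6 (-0.08), SMAD7 (-0.08) and HAMP (0.05) were not called. At an unadjusted p below 0.05 there were 2740 genes. The count was 4 without untreated replicate 1 and 0 without untreated replicate 2 or replicate 2 of BMP2 with Noggin, where ID3 stood at -0.94 and -0.90 and ID1 at -0.92 and -0.94, and 0 with only the arrays compared in the fit. Under cyclic loess 1 gene was called higher and 2 lower. Camera placed 4 lists higher than in untreated cells, with 0 members called by limma, and all were lost with an estimated correlation. Cholesterol genes had a mean of 0.11 (0 adjusted over the list alone, camera FDR = 0.0076, adjusted p = 0.47 with an estimated correlation), immediate-early genes 0.10 (4 adjusted over the list alone, camera FDR = 0.034, adjusted p = 0.47 with an estimated correlation), NF-kappaB genes 0.10 (1 adjusted over the list alone, camera FDR = 0.037, adjusted p = 0.40 with an estimated correlation) and DNA replication genes 0.07 (0 adjusted over the list alone, camera FDR = 0.037, adjusted p = 0.52 with an estimated correlation). In that order their camera FDRs were 0.14, 0.065, 0.069 and 0.92 under cyclic loess and 0.094, 0.11, 0.17 and 0.50 without the dimmer genes. Without untreated replicate 1 the last 3 left the threshold (0.086 each), as did the NF-kappaB list without untreated replicate 2 (0.053), the immediate-early and NF-kappaB lists without replicate 1 of BMP2 with Noggin (0.17 and 0.13) and the DNA replication list without its replicate 2 (0.22).

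BMP6 with Noggin differed from untreated with ID1 (3.39, SE 0.15), ID3 (3.35), SMAD6 (2.54), SLC6A19 (2.44), ATOH8 (2.03) and SMAD7 (1.98) raised, CDH10 (-1.04), RASSF9 (-0.99), EREG (-0.92), LYPD1 (-0.90) and PLK2 (-0.90) lowered, and HAMP at 0.16 (SE 0.10). It had 252 genes called higher and 121 lower, 373 in all, and 179, 184, 197 and 161 without untreated replicates 1 and 2 and replicates 1 and 2 of BMP6 with Noggin. PLK2 lost its call without any of these arrays (-0.94 to -0.86). BMP targets were higher, with 16 of 33 called and 17 adjusted over the list alone (camera FDR = 4.05e-40, adjusted p = 1.2e-04 with an estimated correlation). The other 8 lists past the threshold were lost with an estimated correlation. Notch targets were higher (3 called, 5 adjusted over the list alone, camera FDR = 1.8e-04, adjusted p = 0.16 with an estimated correlation), as were the epithelial-mesenchymal list (4 called, 5 adjusted over the list alone, camera FDR = 0.0025, adjusted p = 0.16 with an estimated correlation), the receptor and SMAD list (4 higher and 1 lower, 6 and 1 adjusted over the list alone, camera FDR = 0.0025, adjusted p = 0.26 with an estimated correlation) and DNA replication genes (1 called, 1 adjusted over the list alone, camera FDR = 0.029, adjusted p = 0.35 with an estimated correlation). NF-kappaB genes were lower, with a mean of -0.16 (1 higher and 4 lower, 1 and 6 adjusted over the list alone, camera FDR = 0.0025, adjusted p = 0.072 with an estimated correlation), as were the stress list, with -0.10 (1 lower, 1 higher and 3 lower adjusted over the list alone, camera FDR = 0.0044, adjusted p = 0.20 with an estimated correlation), hepatocyte genes (1 higher and 1 lower, 1 and 6 adjusted over the list alone, camera FDR = 0.0033, adjusted p = 0.27 with an estimated correlation) and IL-6 and acute-phase genes (0 called by limma, 1 lower adjusted over the list alone, camera FDR = 0.032, adjusted p = 0.27 with an estimated correlation). Without untreated replicate 1 the IL-6, hepatocyte and DNA replication lists left the threshold (0.067, 0.053 and 0.074), and they did without replicate 2 of BMP6 with Noggin (0.24, 0.088 and 0.12). The IL-6 list also did without untreated replicate 2 (0.052), and the stress list without replicate 1 of BMP6 with Noggin (0.060) or the dimmer genes (0.060).

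With RGMc, the genes called against untreated included BMP targets and genes raised by RGMc. In BMP2 with RGMc, ID1 (2.73, SE 0.15), ID3 (2.40), GHR (1.56), the mechanical stress-responsive gene ANKRD1 (1.48) and GPCPD1 (1.47) led the rises, SMAD7 (1.06) and SMAD6 (0.74) were higher, and the thioredoxin-binding protein gene TXNIP (-1.06), ELF5 (-0.85), KLHL24 (-0.85), the taste receptor gene TAS2R10 (-0.75) and SLC6A16 (-0.72) led the falls. HAMP differed by -0.05. SMAD6 lost its call without untreated replicate 1 (0.63) or either array with RGMc (0.74 and 0.73). There were 743 genes higher and 222 lower, 965 in all, and 271, 237, 590 and 207 without untreated replicates 1 and 2 and replicates 1 and 2 of BMP2 with RGMc. In BMP6 with RGMc, ID1 (2.45, SE 0.15), ID3 (1.98), GPCPD1 (1.75), EGR1 (1.54) and CXCL8 (1.49) led, SMAD7 was higher (0.81), SMAD6 missed the threshold (0.50, adjusted p = 0.056), HAMP differed by 0.00, and TXNIP (-1.01), TAS2R10 (-0.93), the microRNA gene MIR32 (-0.87), ELF5 (-0.83) and GRIK1-AS2 (-0.74) fell. MIR32 lost its call without any single array (-0.995 to -0.74) and under cyclic loess (-0.75), and GRIK1-AS2 without untreated replicate 1 (-0.71), untreated replicate 2 (-0.76) or replicate 2 of BMP6 with RGMc (-0.43). There were 903 genes higher and 438 lower, 1341 in all, and 290, 223, 176 and 769 without untreated replicates 1 and 2 and replicates 1 and 2 of BMP6 with RGMc.

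The inhibitors were also set against each other. With BMP2, cells given RGMc kept more of the BMP response than cells given Noggin, with ID1 higher by 3.88 log2 units (SE 0.15, limma adjusted p = 1.6e-08), ID3 by 3.46, GHR by 1.46, DSE by 1.31, ANKRD1 by 1.30, SMAD7 by 1.14 and SMAD6 by 0.82. KLHL24 (-0.92), SOX2 (-0.91), the ADP-ribosyltransferase gene ART4 (-0.91), TAS2R10 (-0.90) and ELF5 (-0.90) were lower, and HAMP differed by -0.09 (SE 0.10). SMAD6 lost its call without any single array of the comparison (0.74 to 0.90). There were 203 genes higher and 159 lower, 362 in all, and 187, 107, 186 and 107 without replicates 1 and 2 of BMP2 with Noggin and replicates 1 and 2 of BMP2 with RGMc. BMP targets were higher with RGMc, with 14 of 33 called and 17 higher and 1 lower adjusted over the list alone (camera FDR = 9.4e-14, adjusted p = 0.0021 with an estimated correlation). So were NF-kappaB genes (7 of 21 called, 11 adjusted over the list alone, camera FDR = 2.5e-10, adjusted p = 0.0021 with an estimated correlation), the stress list (7 of 24 called, 10 adjusted over the list alone, camera FDR = 3.3e-11, adjusted p = 0.0086 with an estimated correlation), immediate-early genes (5 of 26 called, 11 higher and 3 lower adjusted over the list alone, camera FDR = 8.8e-09, adjusted p = 0.016 with an estimated correlation) and TGF-beta targets (2 of 24 called, 6 adjusted over the list alone, camera FDR = 2.0e-07, adjusted p = 0.029 with an estimated correlation). The epithelial-mesenchymal list was higher (2 called, 4 adjusted over the list alone, camera FDR = 0.025, adjusted p = 0.23 with an estimated correlation) and DNA replication genes lower (2 called, 2 adjusted over the list alone, camera FDR = 0.0095, adjusted p = 0.34 with an estimated correlation). Both left the threshold without replicate 2 of BMP2 with Noggin (0.14 and 0.22), and the first did without replicate 2 of BMP2 with RGMc (0.068) or the dimmer genes (0.16).

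With BMP6 the order of the BMP targets was the opposite. HEY1 (-2.05, SE 0.08, limma adjusted p = 7.2e-08), SMAD6 (-2.05), ATOH8 (-1.85), SLC6A19 (-1.79), RASSF5 (-1.64), SMAD7 (-1.17) and ID1 (-0.95) were lower with RGMc than with Noggin, EGR1 (2.37), CXCL8 (1.90), GPCPD1 (1.85), CCL20 (1.65) and EREG (1.54) were higher, and HAMP differed by -0.16 (SE 0.10). There were 1602 genes higher and 1007 lower, 2609 in all, and 1238, 604, 767 and 1362 without replicates 1 and 2 of BMP6 with Noggin and replicates 1 and 2 of BMP6 with RGMc. BMP targets had 18 falls and 3 rises (21 and 4 adjusted over the list alone, camera FDR = 7.5e-14, adjusted p = 0.0020 with an estimated correlation). NF-kappaB genes had 15 rises and 1 fall (15 and 1 adjusted over the list alone, camera FDR = 1.15e-10, adjusted p = 0.0020 with an estimated correlation), the stress list 13 rises and 0 falls (16 and 0 adjusted over the list alone, camera FDR = 4.4e-11, adjusted p = 0.0089 with an estimated correlation), and immediate-early genes 16 rises and 0 falls (18 and 1 adjusted over the list alone, camera FDR = 4.8e-10, adjusted p = 0.011 with an estimated correlation). The NF-kappaB and stress lists differed by means of 0.57 and 0.45 here, and since both were lower with BMP6 and Noggin than in untreated cells (-0.16 and -0.10), part of these differences lay on the Noggin side. Cholesterol genes had 6 rises (6 adjusted over the list alone, camera FDR = 1.1e-05, adjusted p = 0.095 with an estimated correlation). Fibroblast and stellate markers were lower with 1 rise and 2 falls (1 and 6 adjusted over the list alone, camera FDR = 0.048, adjusted p = 0.42 with an estimated correlation, camera FDR = 0.13 under cyclic loess) and left the threshold without replicate 1 of BMP6 with Noggin (0.070) or replicates 1 and 2 of BMP6 with RGMc (0.063 and 0.0501), with a trend and robust prior (0.052) and without the dimmer genes (0.86).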

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

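The tests of whether an inhibitor acted differently on the 2 ligands were among the planned comparisons. Of the further tests that weigh explanations in this part, the 2 on the unequal shares were chosen before their result was seen. Those on Noggin and on the genes raised by RGMc were chosen only after.

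The effect of Noggin differed between the ligands, by a test of the difference itself, for 1061 genes. The named ones were ID1 (4.78), ID3 (4.59), SMAD6 (2.73), SLC6A19 (2.47), ID4 (2.31), SMAD7 (2.00), EREG (-1.31), EGR1 (-1.40), CDH10 (-1.48), RASSF9 (-1.70) and PLK2 (-2.11), as log2 change with Noggin in the BMP6 arm minus that in the BMP2 arm. By the same test the BMP target list differed by a mean of 1.07 (camera FDR = 1.6e-24, adjusted p = 6.4e-04 with an estimated correlation), Notch targets by 0.26, the stress list by -0.20 and the epithelial-mesenchymal list by 0.22, the last 3 lost with an estimated correlation (adjusted p = 0.30 each). Without BMP2 replicate 1 or replicate 2 of BMP2 with Noggin the Notch (FDR = 0.056 and 0.054) and epithelial-mesenchymal (0.12 and 0.054) differences left the threshold, as did the latter without BMP6 replicate 1 (0.058) or replicate 1 of BMP6 with Noggin (0.062). Cyclic loess ended the stress difference (0.071), and leaving out the dimmer genes the stress and epithelial-mesenchymal ones (0.43 and 0.38). For RGMc, 3 lists differed between the ligands by that test with 0 genes called by limma (888 at an unadjusted p below 0.05), BMP ligands and antagonists by 0.0702, NF-kappaB genes by 0.12 and immediate-early genes by 0.13, all lost with an estimated correlation (adjusted p = 0.33, 0.064 and 0.079), and the first also without BMP2 replicate 1 (FDR = 0.055). Of the 13811 probe sets without exactly 1 gene symbol, which the comparisons of genes did not use, 41 were called with BMP2 and 63 with BMP6 against untreated.

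The first pattern weighed is that Noggin lowered the BMP2 response more than the BMP6 response. Too little power in the BMP6 arm is argued against. The rough range of the median change with Noggin over 375 genes ran from -0.122388 to -0.048. It is not an exact 95% interval, as its SD rests on 2 arrays per group. The range lay above the median of -0.30 in the BMP2 arm, but that median was -0.08 without BMP6 replicate 2, inside the range. The argument therefore rests on the direct test of the difference, which called 1061 genes by limma. A small fall with BMP6 stays open because the range lay below 0, though the median of the 375 genes was -0.0166 under cyclic loess. Over all genes the median was -0.035. Exchanged labels between BMP2 and BMP6 arrays stay open, because 0 genes were called between the ligands by limma (1843 at an unadjusted p below 0.05), so the values cannot show which ligand an array received. A different sensitivity of the ligands to Noggin at a 10-fold excess is the biological explanation that the design names, and a lower activity of Noggin in that incubation may give the same values. The labels give the hold before treatment for the inhibitor arms only, and its own effect on each ligand was not tested.

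The second pattern is that RGMc raised inflammatory, immediate-early and stress genes with both ligands. Loss of the BMP signal alone is argued against as the whole cause. The 312 genes that RGMc raised in the BMP6 arm were higher with BMP2 and RGMc than with BMP2 and Noggin by a median of 0.165 (SD between arrays 0.01). A trend with brightness is argued against only for the 22 list members called in both arms, which kept a median of 0.716593 under cyclic loess against 0.745. These members were chosen by their calls on the same arrays, which favours large changes, so the rest of the lists is not covered. An array-wide component shared by the RGMc and BMP2 with Noggin arrays is argued against as the whole cause for these members as a set. They differed between BMP2 with Noggin and untreated by a median of 0.145 (SD between arrays 0.01, 16 of 22 positive). That is less than 0.745 would need at a gap on the first principal component of 13.6 against 18.9. Both yardsticks are rough, since 0.745 was read in a comparison that chose the members and the component includes the RGMc arrays. EGR1 (10.81 in untreated cells, 11.70 with BMP2 and Noggin) and CXCL8 (9.72 and 10.33) differed by more than the median of 0.145. A shared component may add to the rise, as the NF-kappaB and immediate-early lists passed camera between BMP2 with Noggin and untreated too (FDR = 0.037 and 0.034, adjusted p = 0.40 and 0.47 with an estimated correlation). A component of the RGMc preparation that acts apart from BMP binding cannot be told apart from RGMc itself, because no arm had RGMc without a BMP, and the correlation of 0.629304 between the arms is what either would give. The biological explanation, an action of RGMc on these genes, stays open with it.

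The third pattern is that RGMc took away unequal shares of the log2 rises of the 39 genes raised at least 2-fold by both ligands. A share is the log2 fall with RGMc divided by the log2 rise with the ligand. It is not the share of the gained expression that was lost, and the spread of shares holds for that scale only. The median share was 54.5% with BMP2, against untreated replicate 1, and 74.8% with BMP6, against untreated replicate 2. Since the control array differs, part of the gap between these medians may come from it. It does not explain the whole gap, because against the mean of both untreated arrays every gene but DUSP1 still had the larger share with BMP6. Shares of single genes, taken against the mean of both untreated arrays, ran from HEY1 (94.7% and 102%), SNAI1 (89.1% and 102%) and SMAD6 (73.1% and 81.1%) to ID3 (30.7% and 39.8%), ID1 (26.7% and 29.8%), SPRY4 (14.6% and 17.9%) and DUSP1 (14.9% and -2.22%, so not lowered with BMP6). Array noise is argued against, since shares computed in the 2 arms without a common array correlated at a Spearman rho of 0.875911 (95% interval 0.711 to 0.956). Compression of bright probe sets is argued against only as the whole cause, since the shares of the dimmer genes spread as widely (SD ratio 1.22628), and because both values were at hand when that ratio was taken as the deciding one, the rho of share and level is given too: at -0.362 (95% interval -0.645 to -0.042) brighter genes tended to be reversed less, so compression may contribute. A lower sensitivity of some targets to a partial loss of BMP is among the biological hypotheses left beside it. DUSP1 also belongs to the immediate-early list, which was higher with RGMc as a group, so its share need not reflect the BMP response alone.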

How the results depend on the processing

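All tests in this part were planned except the split of the untreated arrays, chosen after the overlap was seen, and values are given where a result moved by more than 1.5 times or past its spread; where no reason is given, the cause was not tested. Probe sets near background vary in the last printed decimals and their differences are compressed, which limits what is called among dim genes.

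Asking for a fold change of at least 1.5 as well can only lower counts. It left 172 genes for BMP2 against untreated, 169 for BMP6, 207 for BMP2 with Noggin against BMP2, 144 for BMP2 with RGMc against BMP2, 167 for BMP6 with RGMc against BMP6, 130 for BMP6 with Noggin against untreated, 139 and 135 for BMP2 and BMP6 with RGMc against untreated, 83 and 258 for RGMc against Noggin with BMP2 and BMP6, and 439 for the difference of the Noggin effects. Testing all probe sets gave 426 for BMP6 against untreated, 392 and 470 for RGMc with BMP2 and BMP6, 0 for BMP2 with Noggin against untreated, 583 and 589 for RGMc against untreated, 238 for RGMc against Noggin with BMP2 and 388 for the Noggin difference. Fitting only the arrays compared, with fewer degrees of freedom, gave 133 for BMP6 against untreated, 138 for RGMc with BMP6, 0 and 226 for Noggin against untreated, 524 for BMP2 with RGMc against untreated, 101 for RGMc against Noggin with BMP2, 296 for the Noggin difference and an overlap of 122 higher and 7 lower. The median reversal was then -0.80 and 0.93 for BMP2 with Noggin (genes higher and lower with the other ligand), -0.51 and 0.36 for BMP2 with RGMc and -0.40 for BMP6 with RGMc, since other genes were selected.

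A trend and robust prior gave 1 gene between the ligands, 1045 for RGMc with BMP2, 9 for BMP2 with Noggin against untreated, 563 for RGMc against Noggin with BMP2, 1635 for the Noggin difference, and reversals of -0.21 and 0.21 (BMP2 with Noggin), -0.11 (BMP2 with RGMc) and -0.28 (BMP6 with RGMc). Without the dimmer genes, RGMc with BMP2 gave 1009, Noggin against untreated 6 and 561, RGMc against Noggin with BMP2 556, and reversals were -0.16 and 0.40, -0.075 and 0.14, and -0.23. The lists past the threshold were 3 (BMP2), 2 (BMP2 with Noggin) and 0 (BMP6 with Noggin), the endothelial list had no gene left, and the BMP ligand list with RGMc and BMP2 turned from lower to higher (signed -log10 p 2.92). Array weights, which were equal within each group, gave 454 for RGMc with BMP6, 8 and 768 for Noggin against untreated, 1451 and 2763 for RGMc against untreated, 4366 for RGMc against Noggin with BMP6, 697 for the Noggin difference, and -0.39 and 0.28 for BMP2 with Noggin. Cyclic loess gave reversals of -0.38 and 0.39 (BMP2 with Noggin), 0.11 (BMP2 with RGMc, lower genes), -0.0166 and -0.0173 (BMP6 with Noggin) and -0.31 (BMP6 with RGMc), and 3 lists with BMP6. The estimated correlation left 1 list of 6 (BMP2), 1 of 5 (BMP6), 1 of 4 and 0 of 1 (Noggin) and 5 of 9 (BMP6 with RGMc).

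Leaving out each array in turn, which leaves 1 array in a group, moved counts between 262 and 332 (BMP2 against untreated), 256 and 1874 (BMP6), 0 and 35 (BMP6 against BMP2), 374 and 866 and 0 and 1115 (Noggin with BMP2 and BMP6), 225 and 741 and 245 and 599 (RGMc), 0 and 4 and 161 and 197 (Noggin against untreated), 207 and 590 and 176 and 769 (RGMc against untreated), 107 and 187 and 604 and 1362 (RGMc against Noggin), 265 and 2902 (Noggin difference) and 0 and 1 (RGMc difference). The overlap ran from 177 to 312 higher and from 13 to 47 lower. With 1 untreated array per ligand, and so fewer calls, it was 153 higher and 17 lower (BMP2 against untreated replicate 1) and 156 and 14 (against replicate 2). Reversals ran from -0.57 to -0.08 and -0.085 to 0.72 (BMP2 with Noggin), -0.34 to -0.02 and -0.085 to 0.21 (BMP2 with RGMc), -0.09 to -0.08 and -0.10 to -0.07 (BMP6 with Noggin), and -0.44 to -0.32 and 0.13 to 0.19 (BMP6 with RGMc). Lists past the threshold ran from 4 to 6 (BMP2), 4 to 10 (BMP6), 2 to 5 and 0 to 1 (Noggin), and 5 to 8 and 8 to 12 (RGMc).

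The replicate number as a block gave 486 genes for BMP2 and 610 for BMP6 against untreated, kept every count within 1.5 times, and ended the calls of 1 named gene, RUNX2, and of 2 lists, the epithelial-mesenchymal difference of the Noggin effects (camera FDR = 0.0508) and fibroblast and stellate markers for RGMc against Noggin with BMP6 (0.0507). Deviations of same-numbered arrays correlated between -0.333 and 0.30 over 21 pairs of groups, 7 above 0.1 and 6 below -0.1. Of the other results with an array left out, 1005 of named genes kept their side of the threshold and 67 lost it, and of lists 1254 kept it, 54 lost it and 52 gained it.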

Other observations

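The test of the hypothesis in this part was chosen before its result was seen, and the gene groups below come from the lists and the naming rule fixed in advance.

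Cells given a BMP with RGMc were also compared with untreated cells by gene group. BMP targets had 15 of 33 higher with BMP2 and RGMc (16 higher and 1 lower adjusted over the list alone, camera FDR = 4.3e-09, adjusted p = 0.0088 with an estimated correlation) and 12 higher and 1 lower with BMP6 and RGMc (16 and 4 adjusted over the list alone, camera FDR = 2.4e-04, adjusted p = 0.045 with an estimated correlation). TGF-beta targets, which include matrix and cytoskeleton genes, had 9 of 24 higher with BMP2 and RGMc (10 adjusted over the list alone, camera FDR = 2.7e-04, adjusted p = 0.12 with an estimated correlation) and 9 higher and 1 lower with BMP6 and RGMc (11 and 5 adjusted over the list alone, camera FDR = 0.0017, adjusted p = 0.16 with an estimated correlation). Against BMP2 alone that list did not pass (2 higher, 7 higher and 2 lower adjusted over the list alone, camera FDR = 0.15, adjusted p = 0.47 with an estimated correlation), so a difference from BMP2 was not shown for it. Against BMP6 alone it passed (6 higher and 1 lower, 7 and 1 adjusted over the list alone, camera FDR = 0.0023, adjusted p = 0.14 with an estimated correlation), and the test of the difference between the arms did not with all arrays (camera FDR = 0.0997, adjusted p = 0.52 with an estimated correlation). That outcome turned on single arrays, since the difference passed without BMP2 replicate 2 (camera FDR = 0.020), replicate 2 of BMP2 with RGMc (0.041) or replicate 2 of BMP6 with RGMc (0.014). NF-kappaB genes had 11 of 21 higher in either arm (camera FDR = 1.3e-09 and 1.7e-10, adjusted p = 0.0037 and 0.0030 with an estimated correlation), with 11 higher and 1 lower, and 12 and 1, adjusted over the list alone. Immediate-early genes had 12 and 16 of 26 higher (15 and 18 higher, and 0 and 1 lower, adjusted over the list alone, camera FDR = 4.3e-09 and 1.7e-10, adjusted p = 0.018 and 0.015 with an estimated correlation), and the stress list 8 and 11 of 24 (11 and 11 adjusted over the list alone, camera FDR = 5.9e-07 and 1.6e-09, adjusted p = 0.028 and 0.015 with an estimated correlation). Cholesterol genes had 1 and 2 of 19 higher (1 and 3 adjusted over the list alone, camera FDR = 0.0022 and 1.7e-04, adjusted p = 0.25 and 0.15 with an estimated correlation), the first lost without the dimmer genes (0.064). Fibroblast and stellate markers were lower with BMP6 and RGMc, with 1 of 15 higher and 2 lower (1 and 6 adjusted over the list alone, camera FDR = 0.032, adjusted p = 0.48 with an estimated correlation). That list left the threshold under cyclic loess (0.13), with a trend and robust prior (0.052), without the dimmer genes (0.97), without untreated replicate 2 (0.076) and without replicate 1 or 2 of BMP6 with RGMc (0.0508 and 0.0509). TXNIP, a gene induced by glucose, fell in both (-1.06 and -1.01), but it fell with BMP2 alone too (-0.70) and stood at -0.38 with BMP6 alone, and the change with RGMc was called with BMP6 (-0.64) and not with BMP2 (-0.36, limma adjusted p = 0.25). GPCPD1, a glycerophosphodiesterase gene, rose in both (1.47 and 1.75).

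A hypothesis of this re-analysis was that the genes that respond most to BMP are lowered least by RGMc. For 39 genes the rise with BMP6 and the share reversed in the BMP2 arm were computed on the log2 scale without a common array. Their Spearman rho was 0.018018 (95% interval -0.328 to 0.348). An interval that includes 0 had been set to count against the hypothesis, which was too wide a condition, because this interval also allows a weak relation of either sign. The hypothesis stays undecided.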
